A study of Danio rerio with 6 samples.

How the data were processed

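Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on wild-type whole zebrafish embryos at 24 hours after fertilization, with an antibody against H3K4me1 or H3K4me3, beside input DNA that had not been immunoprecipitated. There were 6 libraries, 2 in each of 3 groups. Per the labels' protocols, sonicated chromatin was used, the libraries were amplified for 15 PCR cycles, and fragments of about 250 bp were taken from a gel and sequenced on a Genome Analyzer. The titles of 3 libraries carry the number 2 and those of the other 3 carry none, so the latter are called replicate 1 here. The labels do not say whether the libraries of a group came from separate collections of embryos, so the spread between them may be partly technical.

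The deposited files hold 1 line per aligned read with its chromosome, its start and end positions and its strand. They hold no measured signal and no enriched regions, and nothing in them had been normalised. MACS 1.3.6, a peak caller, is named in the submitters' processing notes; the aligner, its settings and the enriched regions called by the authors are not given in the sources used here. The unplaced contigs named in the deposited files carry a Zv7 prefix in the 3 libraries of replicate 1 and a Zv8 prefix in the 3 libraries of replicate 2. The file names of replicate 2 say zv7, but on chromosome 4 its reads reach 71.7 Mb against 42.6 Mb in replicate 1, so the sets are not on 1 assembly and the prefix was followed. Zv7 and Zv8 are successive assemblies of the zebrafish genome, and the same position in them is not the same sequence. In all 3 deposited files of replicate 2 the read names contain the word input, those of the ChIP libraries too. Group membership was taken from the labels. Any 2 of the 6 libraries shared at most 0.118% of short runs of read spacings, so the libraries of a group were not the same reads deposited again.

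Because of the assemblies, no position was compared between replicates. The tests fixed before the data were examined had assumed positions shared by all 6 libraries: a linear model (limma) over 1 kb tiles with 2 libraries per group, regions found in both replicates, and each ChIP library against the input of the other replicate. These were not run. Each set of 3 libraries on 1 assembly was analysed on its own, and the values of both sets are given side by side, or as mean ± SD (n = 2) for summaries that do not depend on position. Within a set each group has 1 library, so a test on its reads compares those libraries and not the groups. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333. No annotation of Zv7 or Zv8 was used here, so regions are given by position and no gene is named; the planned tests at promoters and of gene lists were not run.

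Reads on the 25 numbered chromosomes were used, and reads at the same position and strand were counted once, which left between 6704188 and 11765067 reads per library. Fragment length was taken as the distance from 60 to 400 bp at which reads of opposite strands coincided most often, which was between 75 and 130 bp in the 6 libraries. Shorter distances, near the read length, were left out; in the input of replicate 1 reads coincided more often at 30 bp (1.72 times the level at 400 bp and above) than at the 120 bp used (1.48 times). All 3 libraries of replicate 2 had a step from 70 to 75 bp. It ran from 1.39 to 1.48 for H3K4me1, from 1.54 to 1.58 for H3K4me3 and from 1.40 to 1.44 for input. The 75 bp taken for H3K4me3 and input in replicate 2 may therefore not be a fragment length. All lengths taken were below the 250 bp given in the labels. Each read was moved by 50% of the length taken for its library, towards the fragment's middle. Counts per window were made here from these positions. Chromosome lengths were taken as the last aligned base of each set.

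Enriched regions were called in each ChIP library against the input of its own set with a one-sided Poisson test of the reads in windows of 600 bp, moved in steps of 200 bp. The rate was the largest of the genome-wide rate and the input rates over 5 kb and 10 kb around the window, scaled by total reads. Windows with p of at most 1e-05 were merged. This follows the local-rate idea of MACS but is not that program. The same call with input and ChIP exchanged was made for comparison. Since scaling was by total reads, the median 1 kb tile held less H3K4me3 than input (log2 ratio -0.32 and -0.36). The exchanged count for H3K4me3 can therefore overstate the background of the call. RPM stands for reads per 1000000 reads used. Fold over input is the ratio of RPM, and its 95% interval is the exact (Clopper-Pearson) binomial interval. Shares have 95% Wilson intervals. All intervals cover counting error only, and amplified reads are not independent molecules. Overlap means at least 1 bp in common. Random placement moved each region of the other mark to a random start on its own chromosome, 1000 times with a fixed seed, for a two-sided permutation p that cannot fall below 0.002. Distances used 200 placements, with placed regions that fell on an H3K4me3 region left out, a choice made after a first set of distances had been seen. Mean profiles used bins of 100 bp up to 5 kb from region centres, with the centre as the middle 500 bp and the flanks as 1 to 2 kb on both sides. For 1 kb tiles with a mean of at least 5 reads per library, log2(CPM + 0.5) was compared between libraries of a set, and tiles with a log2 difference of at least 1 in size were counted. Tiles with over 10 times the median input were left out. The count that Poisson noise alone would give was simulated at the pooled rate of both libraries.

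The regions named were taken by a rule fixed before the data were examined, applied in each set: the 5 with the largest fold (reads plus 1) in each of 3 classes, the 5 widest per mark, and the 3 chromosomes with the most and the 3 with the fewest regions per megabase, by the mean of both sets. The methods were tested on simulated reads with 200 planted regions of 1 kb at each fold. Their background was the input smoothed over 10 kb, so they lack the fine structure of the real input, and planted folds are relative to this background and not to a region's own input. With the depth of replicate 1, 6% of H3K4me1 regions planted at 2-fold, 84.5% at 4-fold and 99.5% at 8-fold were called, and 2.5%, 61.5% and 99.5% of H3K4me3 regions. In replicate 2 the shares were 6%, 80% and 99.5% for H3K4me1 and 4.5%, 70% and 99% for H3K4me3. Between 37 and 70 regions were called where none had been planted. The counting of overlaps was checked on the planted positions themselves and not on called regions. Overlap made to be 50% came out as 50.2% in both sets, and the share was 0.167% where none had been made. This does not test how well overlap is recovered from reads.

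Alternatives fixed before the data were examined were p of at most 1e-08, all reads counted, all libraries thinned to 6704188 reads (for the numbers of regions), overlap of at least 50% of the shorter region, and for tiles another scaling (median of ratios over 10 kb tiles), a pseudocount of 0.1, no filter, 2 kb tiles and high-input tiles kept, as well as each set alone. Added after the data had been seen were a rate that also takes the input of the window itself and an input scaled to the median 10 kb tile, thinned libraries called at p of at most 1e-08, and, for the overlap, thinned libraries and all reads counted. The distances, the profiles by region width, the densities along chromosomes, the regions on contigs and the tile counts without a test were not part of the design fixed beforehand. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Reads on unplaced contigs and mitochondrial reads entered none of the regions, profiles or tiles.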

Results

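The series maps 2 histone marks in wild-type whole zebrafish embryos at 24 hours after fertilization, to find putative regulatory elements. H3K4me3, trimethylation of lysine 4 of histone H3, is best known at promoters, and H3K4me1, its monomethylation, at enhancers and around promoters. There were 2 H3K4me1 libraries, 2 H3K4me3 libraries and 2 input libraries. By the names of their contigs, the libraries of replicate 1 were aligned to the Zv7 assembly and those of replicate 2 to Zv8, although the file names of the latter say zv7, so positions are given per set and were not matched between sets. The H3K4me1 libraries held 13548123 and 11989430 aligned reads in replicates 1 and 2, the H3K4me3 libraries 7846091 and 9345594, and the input libraries 8576638 and 12933240. Reads repeating another read's position and strand made up 11.5% and 9.08% of H3K4me1 reads on the numbered chromosomes, 6.91% and 7% of H3K4me3 reads, and 6.72% and 1.26% of input reads.

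The first comparison asks where H3K4me3 was enriched over input. H3K4me3 was concentrated in 25282 ± 3441 regions per library (SD, n = 2), 22849 in replicate 1 and 27715 in replicate 2. These regions had a median width of 1200 bp in both replicates and covered 2.41% and 2.75% of the numbered chromosomes. They held 32.6% of the H3K4me3 reads in replicate 1 (95% Wilson interval 32.5% to 32.6%) and 32.8% in replicate 2 (32.7% to 32.8%), against 4.70% and 4.33% of the input reads, a ratio of 7.25 ± 0.460 (SD, n = 2). The widest region in replicate 1 spanned 10.4 kb on chromosome 13 (Zv7, 4565201 to 4575600), with 1040 H3K4me3 reads and 100 input reads, 11.3-fold over input (95% interval 9.22 to 14.1). In replicate 2 the widest spanned 13.6 kb on chromosome 15 (Zv8, 46123801 to 46137400), at 10.5-fold (8.15 to 13.7), followed by 12.4 kb on chromosome 5 (50773601 to 50786000), at 9.60-fold (8.30 to 11.2), and 11.4 kb on chromosome 13 (5881001 to 5892400), at 10.4-fold (8.92 to 12.1). Chromosomes 3, 5 and 13 each had one of the 5 widest regions in both sets, but whether these are the same regions was not tested. On chromosome 3 they lay at 23073001 to 23080200 in Zv7, with H3K4me1, and at 126401 to 136200 in Zv8, without it. The region of 8.4 kb on chromosome 9 (Zv7, 43262201 to 43270600), also among the 5 widest of replicate 1, had 2922 H3K4me3 reads against 1355 input reads, 2.35-fold. With ChIP and input exchanged, the same call gave 12482 and 18491 regions at p of at most 1e-05, but 1290 and 1625 at 1e-08, where 17460 and 18975 H3K4me3 regions were called.

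H3K4me1 regions had a smaller rise over input than H3K4me3 regions in both sets, and at p of at most 1e-05 there were more of them. There were 46060 ± 2061 H3K4me1 regions per library (SD, n = 2), 47517 in replicate 1 and 44603 in replicate 2, with a median width of 1000 bp in both. They held 18.5% of the H3K4me1 reads in replicate 1 (18.5% to 18.6%) and 18.2% in replicate 2 (18.2% to 18.2%), against 8.26% and 6.40% of the input reads, a ratio of 2.54 ± 0.422 (SD, n = 2). The H3K4me1 libraries were deeper, which lets weaker regions be called. With all libraries thinned to 6704188 reads, a comparison added after the results had been seen, the median fold of a region was 2.44 and 3 for H3K4me1 and 5 and 5.5 for H3K4me3. The regions then covered 28.9 and 29.8 Mb for H3K4me1 and 30.7 and 32.9 Mb for H3K4me3, with a ratio of shares of 2.56 and 3.27 against 6.94 and 8.12. Each mark's regions were chosen by its own reads, so these values describe the called regions. Thinned, 30922 H3K4me1 and 23848 H3K4me3 regions were called on average at p of at most 1e-05, but 13832 and 17544 at 1e-08, so which mark had more regions depended on depth and threshold. The widest region of replicate 1 spanned 7.8 kb on chromosome 13 (Zv7, 4495601 to 4503400), where 505 H3K4me1 reads stood against 88 input reads, 3.79-fold (3.02 to 4.81). It lay 61.8 kb from the widest H3K4me3 region of that set. In replicate 2 the widest spanned 17.2 kb on chromosome 2 (Zv8, 31950001 to 31967200), at 3.59-fold (3.17 to 4.07), and the next 10 kb on chromosome 22 (18885801 to 18895800), at 4.79-fold (4.06 to 5.69). With ChIP and input exchanged, the call gave 8697 and 10700 regions. Unthinned, the number averaged 25003 at p of at most 1e-08, where the exchanged call gave 852 and 925, and 28121 when the input of the window itself was added to the rate, an alternative chosen after seeing the data.

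**Figure D1:**
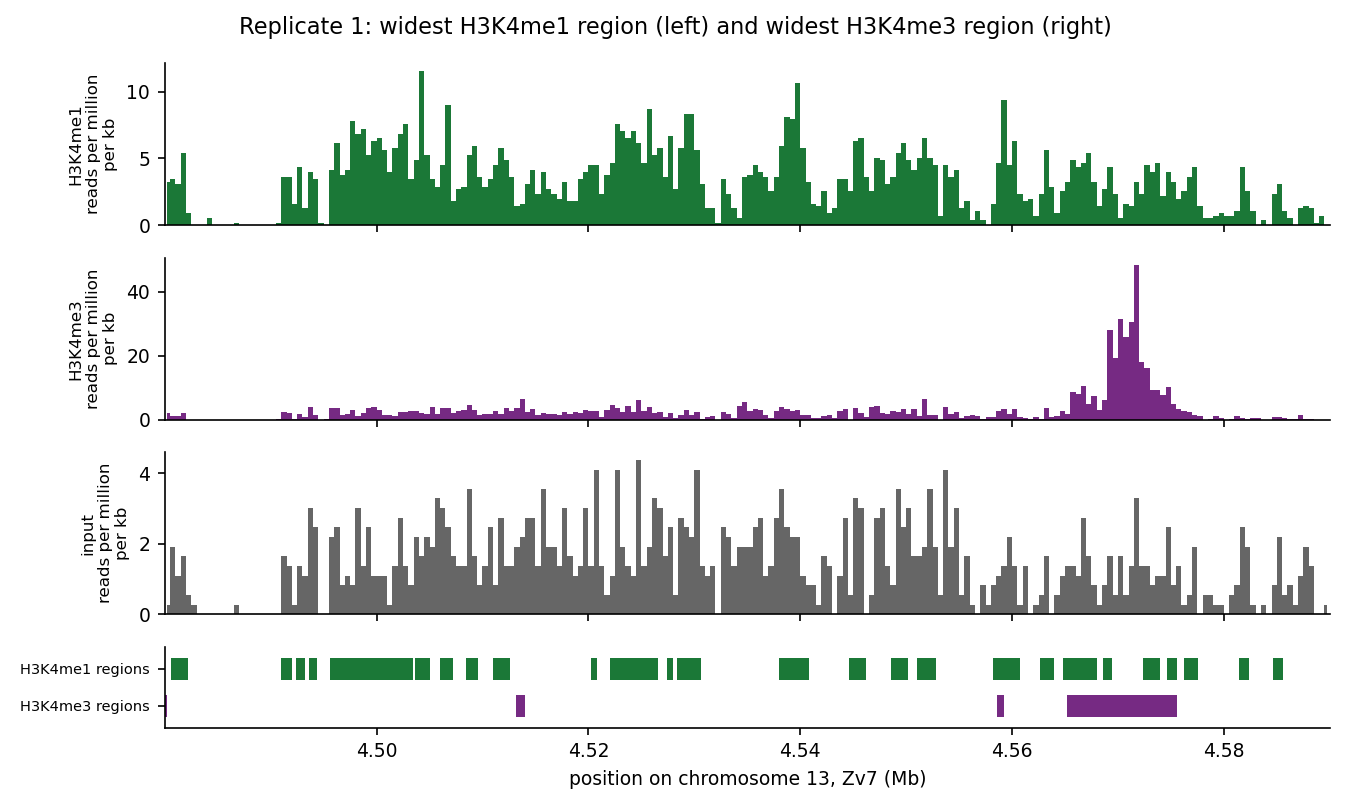
RPM per kb in bins of 500 bp along 110 kb of chromosome 13 (Zv7, 4480001 to 4590000) in the 3 libraries of replicate 1, with the called regions as bars below. H3K4me3 reached 48.3 in the widest H3K4me3 region, while 26 H3K4me1 regions were spread over the span and input stayed at or below 4.38.

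The next comparison asks how often both marks lay at the same place. H3K4me3 regions overlapped an H3K4me1 region in 64.1% of cases in replicate 1 (63.5% to 64.7%) and 52.8% in replicate 2 (52.2% to 53.4%), or 58.4% ± 8.03 (SD, n = 2). Randomly placed H3K4me1 regions gave 8.41% and 7.63%, so the overlap was 7.62 and 6.91 times that of placement, with a permutation p of 0.002 in each set, the smallest that 1000 placements can give. Seen from the other mark, 32.5% and 34.8% of H3K4me1 regions overlapped an H3K4me3 region, against 4.15% and 4.83% after placement. Placement is not the overlap to expect without a shared mark, since both marks were called against the same input and windows outside regions with many input reads also held more reads of both marks. With the input of the window itself in the rate, chosen after seeing the data, the overlap was 54.8% and 49.2%, against 4.67% and 5.23% after placement. With all libraries thinned to one depth, chosen after seeing the data, the overlap averaged 47.9%, or 34.0% at p of at most 1e-08, where placement gave 2.38% and 2.42%.

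Most H3K4me1 regions had no H3K4me3 region on them. These H3K4me1-only regions numbered 32090 (67.5%) in replicate 1 and 29084 (65.2%) in replicate 2. Their median fold over input was 1.98 and 2.52 for H3K4me1 and 0.793 and 0.981 for H3K4me3. Input itself was 2.65 and 1.77 times higher at their centres than at their flanks, and the call did not use the window's own input. With that input in the rate, chosen after seeing the data, 26123 and 30119 H3K4me1 regions were called in all. Of these, 41.4% and 39.8% overlapped an H3K4me3 region, so the size of the H3K4me1-only class depended on this choice. H3K4me3 regions with H3K4me1 numbered 14652 and 14625, with a median width of 1400 bp in both sets, a median H3K4me3 fold of 5.72 and 6.60 and a median H3K4me1 fold of 2.18 and 2.72. The 8197 and 13090 H3K4me3-only regions were narrower, with medians of 1000 and 800 bp, and had a median H3K4me3 fold of 3.43 and 3.57 beside a median H3K4me1 fold of 1.27 in replicate 2 and, in replicate 1, one near 1 (25th and 75th percentiles 0.660 and 1.58). The number of H3K4me3-only regions differed between the sets by more than that of the other classes. In thinned libraries, chosen after seeing the data, 50.3% of 22779 and 45.5% of 24918 H3K4me3 regions overlapped an H3K4me1 region. The shares of H3K4me3-only regions were then closer between the sets. With ChIP and input exchanged, 12482 and 18491 regions were called, more than this class holds, although that count can overstate the background. Part of the class may therefore be marginal calls. Medians of folds add 1 read to each count.

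Of the 5 regions per class and set with the largest folds, those with the most input reads are described first, since their folds have the narrowest intervals. Those with both marks in replicate 1 included 1.8 kb on chromosome 9 (Zv7, 6637401 to 6639200), with 261 H3K4me3, 48 H3K4me1 and 6 input reads, 47.4-fold for H3K4me3 (21.5 to 130) and 5.28-fold for H3K4me1 (2.26 to 15.1), and 2.4 kb on chromosome 14 (Zv7, 27519001 to 27521400), with 195 H3K4me3, 56 H3K4me1 and 4 input reads, 53.1-fold for H3K4me3 (20.4 to 197) and 9.24-fold for H3K4me1 (3.42 to 35.1). In replicate 2 a region of 2.4 kb on chromosome 2 (Zv8, 56694601 to 56697000) had 512 H3K4me3 and 12 input reads, 62.8-fold (35.6 to 122), with H3K4me1 at 4.28-fold (2.22 to 8.90). The region ranked first in replicate 1, on chromosome 14 (Zv7, 51349601 to 51351200), had 93 H3K4me3 reads and 0 input reads. Its H3K4me3 fold had a lower bound of 26.9. Other large folds rested on 2 or 3 input reads. In replicate 1 these were 61.0-fold (16.5 to 510) on chromosome 13 (Zv7, 18521001 to 18522400) and 55.2-fold (18.5 to 271) on chromosome 1 (Zv7, 8979401 to 8981000). In replicate 2 they were 110-fold (29.8 to 914) on chromosome 21 (Zv8, 1813801 to 1815400) and 93.4-fold (25.3 to 780) on chromosome 8 (Zv8, 42171201 to 42172600). Of the H3K4me3-only class, 2.8 kb on chromosome 16 (Zv8, 6840201 to 6843000) held 809 H3K4me3 and 20 input reads, 59.5-fold (38.3 to 98.0), and its H3K4me1 reads were 2.33-fold over input (1.33 to 4.21) without reaching the call. Larger folds of this class in replicate 2 were 88.3 (29.7 to 432) on chromosome 7 (Zv8, 7404001 to 7405600) and 77.0 (25.9 to 377) on chromosome 8 (Zv8, 55440201 to 55441600), with 3 input reads each, and 110 (19.2 to 4416) on chromosome 14 (Zv8, 12666401 to 12667600), with 1. In replicate 1 all 5 of the top H3K4me3-only regions had 0 input reads, such as 1.2 kb on chromosome 22 (Zv7, 8246801 to 8248000) with 96 H3K4me3 and 15 H3K4me1 reads. The largest H3K4me1-only fold in replicate 1 was at 1.2 kb on chromosome 16 (Zv7, 26356001 to 26357200), with 56 H3K4me1 reads, 10 H3K4me3 reads and 1 input read, 37.0-fold (6.37 to 1486). H3K4me3 was 10.9-fold over input there (1.55 to 473), without reaching the call. In replicate 2 the largest H3K4me1-only fold was at 0.6 kb on chromosome 10 (Zv8, 3116801 to 3117400), with 23 H3K4me1 reads, 7 H3K4me3 reads and no input read. The lower bound of its H3K4me3 fold was 2.12. At this depth a few input reads decide such folds, as the intervals show.

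The position of H3K4me1 relative to H3K4me3 was read from mean profiles around H3K4me3 regions. H3K4me3 rose to 8.13 times input at the centre in replicate 1 and 9.14 times in replicate 2, against 1.31 and 1.34 at 4 to 5 kb. H3K4me1 was also above input there, at 1.73 and 2.18 times at the centre, against 1.09 and 1.14 at 4 to 5 kb. In replicate 1 it was highest 600 bp from the centre (1.92 times input) with a dip to 1.73 in the middle, whereas in replicate 2 it was highest at the centre (2.25 times). Around the 7745 and 8798 H3K4me3 regions of at least 1600 bp both sets had the dip in this ratio: H3K4me1 was highest 800 bp from the centre in replicate 1 (2.27 times input, against 1.73 at the centre) and 500 bp from it in replicate 2 (2.61 against 2.39). Around the narrowest regions, 5742 and 8769 at or below the 25th percentile of width, it was highest 100 bp from the centre in replicate 1 (1.39 against 1.36) and at the centre in replicate 2 (1.68). The ratio of centre to flank after division by input was 1.34 and 1.69 for H3K4me1 and 5.08 and 5.98 for H3K4me3. The input libraries themselves had more reads at the centre than at the flanks, by 2.33 times in replicate 1 and 1.59 times in replicate 2, and over all H3K4me3 regions the dip of replicate 1 appeared only after division by input. Before it, H3K4me1 was higher at the centre in both sets, at 3.59 and 3.22 RPM per kb, than 500 bp to the left, at 2.06 and 1.89. In the regions of at least 1600 bp H3K4me1 before division was higher at the centre than at the flanks, by 2.54 and 2.42 times. These flanks lie farther out than the 800 and 500 bp at which the ratio was highest. The undivided signal at those distances was not taken for these regions. Whether their dip came from division by input therefore stays open. No p is given, and an exact permutation test of 2 against 2 libraries could not fall below 0.333.

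**Figure D2:**
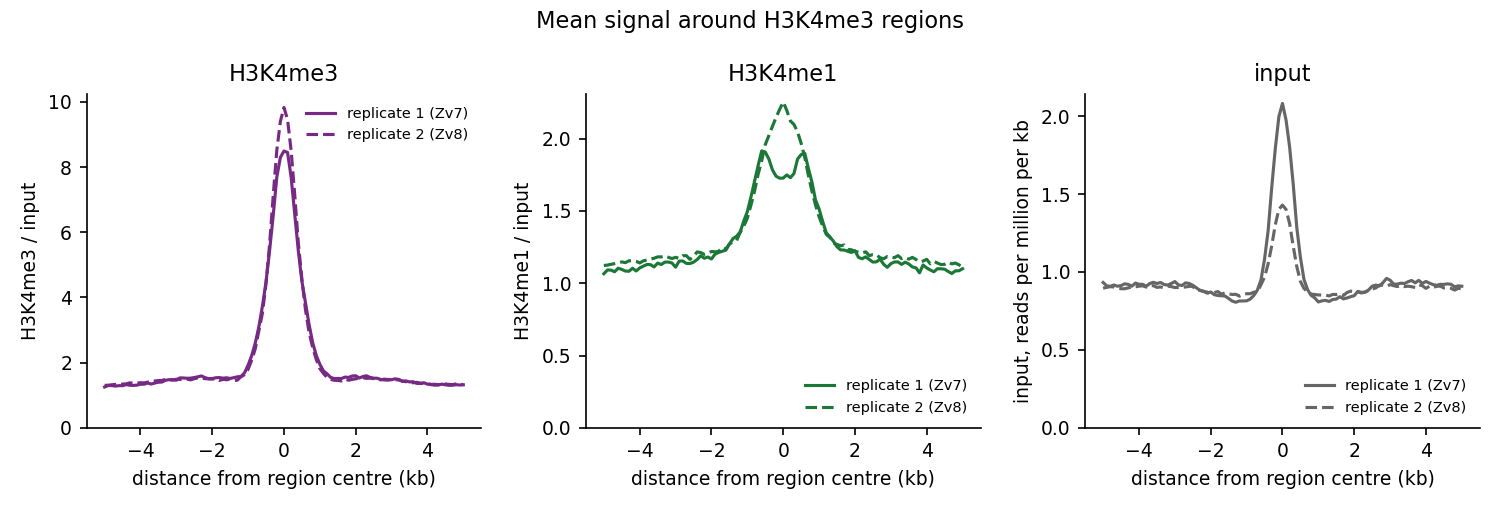
Mean H3K4me3 to input ratio, H3K4me1 to input ratio and input RPM per kb against the distance in kb from the centre of H3K4me3 regions, 22849 in replicate 1 (solid lines) and 27715 in replicate 2 (dashed lines). The ratio for H3K4me1 dipped to 1.73 at the centre in replicate 1 and peaked at 2.25 there in replicate 2, while input rose at the centre in both.

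H3K4me1-only regions lay nearer to H3K4me3 regions than placement at random would put them. Their median distance to the nearest H3K4me3 region was 17.4 kb in replicate 1 and 12.8 kb in replicate 2, against 26.4 and 23.2 kb for placed regions, and no placement of 200 went below 25.7 and 22.6 kb. Within 10 kb lay 35.2% and 43.4%, against 26.1% and 29.0% for placed regions, and within 50 kb 80.3% and 86.1%, against 68.2% and 71.0%. Over 100 kb away lay 6.44% and 4.11%. Placement also used stretches where no read aligned and no region can be called, such as 52000001 to 53000000 of chromosome 4 in Zv8, with input of 0. This can lengthen the placed distances, so the difference from placement does not show a link between the marks.

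**Figure D3:**
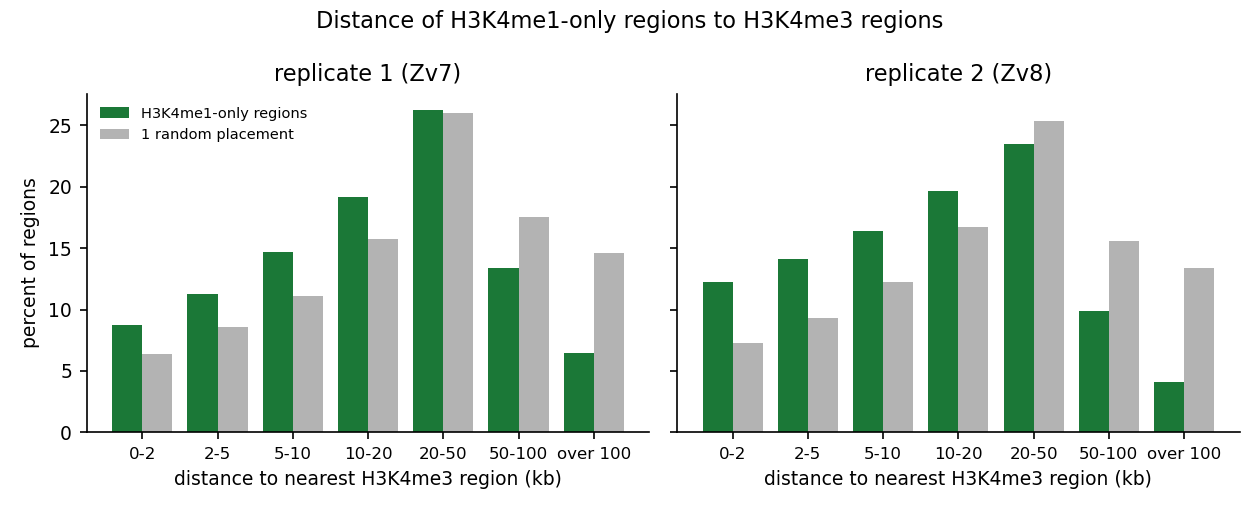
Percent of H3K4me1-only regions by distance in kb to the nearest H3K4me3 region (green bars), beside 1 random placement (grey bars), in replicate 1 (left) and replicate 2 (right). The regions exceeded placement in every class up to 20 kb and fell below it beyond 50 kb in both sets. Placement also used stretches where no read aligned.

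Region density differed between chromosomes. H3K4me3 regions were densest on chromosome 22, with 24.6 ± 2.87 per Mb (SD, n = 2), followed by chromosomes 23 (22.7 ± 3.82) and 25 (22.4 ± 2.75), and sparsest on chromosomes 4 (14.9 ± 3.20), 12 (17.0 ± 1.52) and 18 (17.5 ± 3.42). H3K4me1 regions were densest on chromosomes 23 (44.8 ± 1.40 per Mb), 7 (41.0 ± 5.81) and 13 (41.0 and 38.9 in the replicates) and sparsest on chromosomes 4 (28.2 ± 10.6), 14 (30.5 ± 0.678) and 1 (30.8 ± 3.62). Across the 25 chromosomes the densities of the sets correlated, with r = 0.654 (permutation p = 0.00048, adjusted 0.0012) and rho = 0.798 (permutation p = 1e-05, the smallest possible) for H3K4me1, and r = 0.657 (permutation p = 0.0006, adjusted 0.0012) and rho = 0.766 (permutation p = 2e-05) for H3K4me3. Without the 2 chromosomes farthest from the median of replicate 1, r was 0.541 and 0.572. The densities of H3K4me1-only and H3K4me3 regions had no detected correlation, with r = -0.0697 in replicate 1 (permutation p = 0.741, adjusted 0.741) and 0.378 in replicate 2 (permutation p = 0.0629, adjusted 0.0839), with rho of -0.0592 (permutation p = 0.778) and 0.115 (permutation p = 0.582) and r of -0.201 and -0.164 without the 2 farthest. Adjustment (Benjamini-Hochberg) covered these 4 relations, and chromosomes are not independent replicates.

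**Figure D4:**
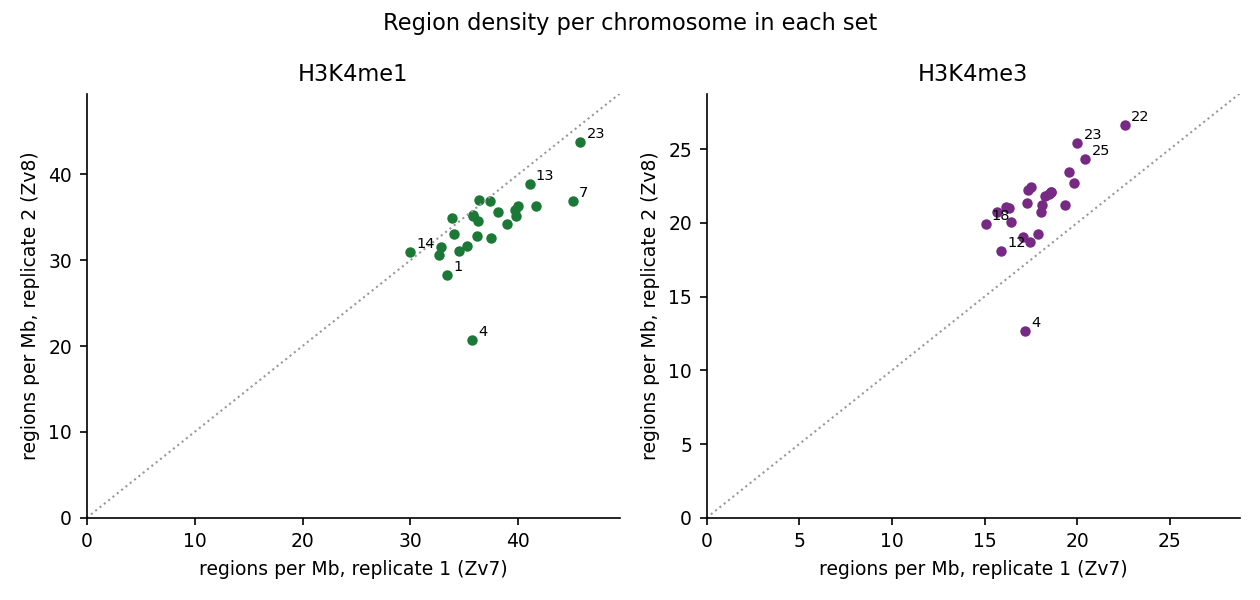
H3K4me1 (left) and H3K4me3 (right) regions per Mb on each of the 25 chromosomes, replicate 1 on the horizontal and replicate 2 on the vertical axis, with equality as a dotted line and the densest and sparsest chromosomes numbered. Chromosome 4 stands apart, at 35.7 and 20.7 H3K4me1 regions per Mb and at 17.2 and 12.7 H3K4me3 regions per Mb.

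Chromosome 4 had the lowest density of both marks by the mean of the sets, and this came from the Zv8 set, in which it ranked last for both marks against 17 and 18 in the Zv7 set. Reads reached 42.6 Mb on chromosome 4 of Zv7 and 71.7 Mb on that of Zv8. From 36000001 to the end of chromosome 4 of Zv8 there were 2.05 H3K4me1 and 6.11 H3K4me3 regions per Mb, against 39.2 and 19.1 before that position. Input was 742 RPM per Mb before 36000001 and 125 after it. This position is the middle of the chromosome and not a boundary seen in the data. Sparse megabases began earlier, with 2 H3K4me1 regions and input of 79.6 RPM in that from 27000001. The megabase from 32000001 held 50 H3K4me1 regions. That from 66000001 held 21 H3K4me1 and 53 H3K4me3 regions, with input of 500 RPM. From 21000001 on in Zv7, the middle there, the densities of H3K4me1 and H3K4me3 regions were 19.4 and 14.0 per Mb, against 52.5 and 20.4 before.

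**Figure D5:**
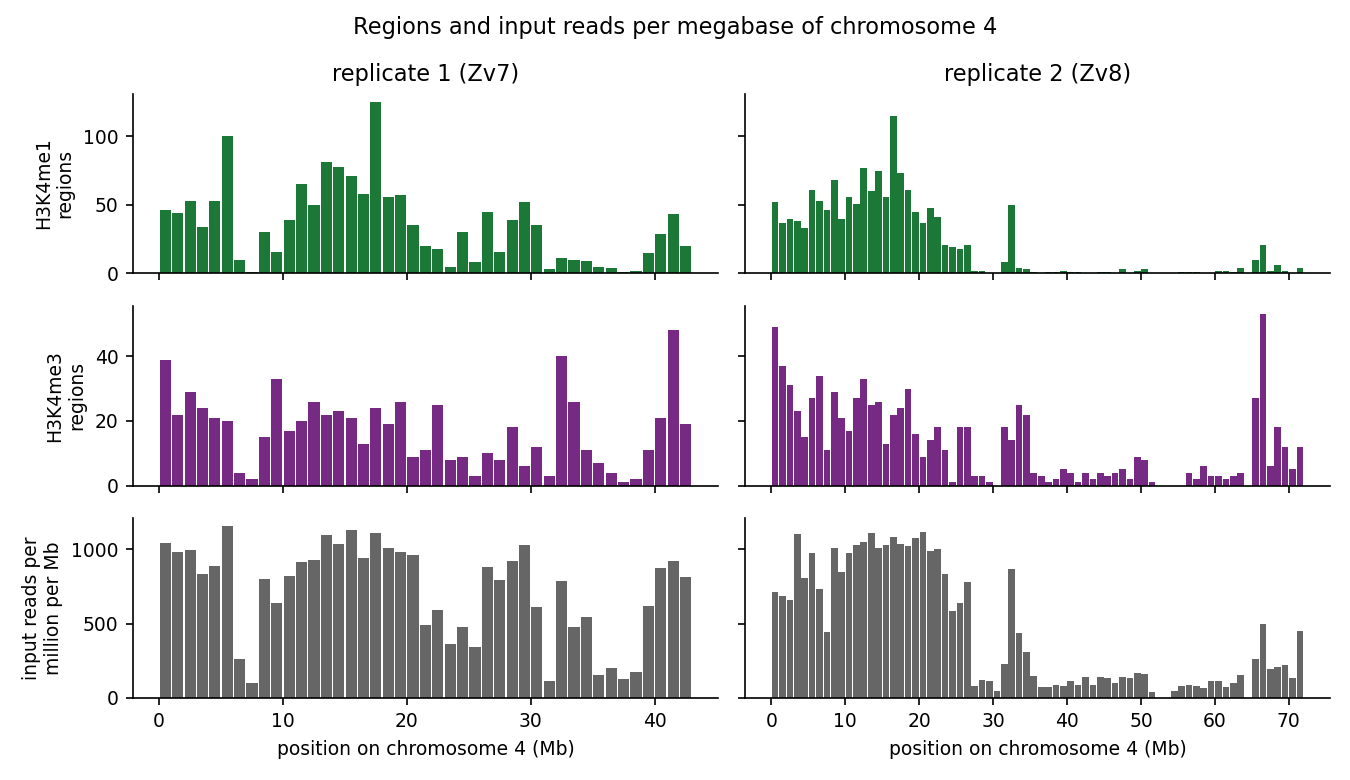
Number of H3K4me1 regions, number of H3K4me3 regions and input RPM per Mb in each megabase of chromosome 4, by position in Mb, in replicate 1 (Zv7, left) and replicate 2 (Zv8, right). In replicate 2 input reads and H3K4me1 regions are sparse in most megabases from 27000001 on. From the middle of the chromosome, 36000001, 73 H3K4me1 and 218 H3K4me3 regions were called.

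The signal was last compared in 1 kb tiles between libraries of a set. H3K4me1 was at least 2-fold above input in 42641 of 690324 tiles in replicate 1 and 43913 of 794450 in replicate 2, and as far below it in 29395 and 37127. H3K4me3 was at least 2-fold above input in 43166 and 47494 tiles and below in 104030 and 125114, and it exceeded H3K4me1 in 40201 and 43214 tiles and lay below it in 96896 and 93076. Counting noise alone would give 13254 and 6032 tiles with H3K4me1 above input, 17893 and 8124 with H3K4me3 above input, and 10127 and 11134 with H3K4me3 above H3K4me1. These counts have no replicate test. Scaling by the median of ratios moved the median log2 ratio of H3K4me3 to input from -0.32 to -0.04 in replicate 1 and from -0.36 to -0.07 in replicate 2. It raised the share of higher tiles among those that differed from 59.2% and 54.2% to 74.9% and 71.2% for H3K4me1 over input, from 29.3% and 27.5% to 58.6% and 54.1% for H3K4me3 over input, and from 29.3% and 31.7% to 50.5% and 52.2% for H3K4me3 over H3K4me1, so which direction prevailed for H3K4me3 depended on the scaling. For H3K4me1 over input it depended on the pseudocount: with 0.1 in place of 0.5, 75934 and 78747 tiles were higher and 79061 and 106317 lower. Across 10 kb tiles within a set, the log2 CPM of H3K4me1 and H3K4me3 correlated with r = 0.821 and 0.854 (rho 0.762 and 0.792), that of H3K4me1 and input with r = 0.905 and 0.922 (rho 0.776 and 0.805), and that of H3K4me3 and input with r = 0.757 and 0.779 (rho 0.673 and 0.657); tiles are not independent replicates.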

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

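Enriched regions were also found on unplaced contigs, sequences not assigned to a chromosome, which entered no comparison above. Whether a number exceeded the exchanged call was judged against counting error by a rule added after the numbers had been seen. On contigs of 5 kb or more, replicate 1 had 4009 H3K4me1 regions, against 1342 with ChIP and input exchanged, and 2399 H3K4me3 regions against 1903. Replicate 2 had 3329 H3K4me1 regions against 1694. The H3K4me3 regions of replicate 2 did not exceed the exchanged call, at 2868 against 2852, although at p of at most 1e-08 there were 1825 against 331. Reads on contigs were also scaled by their totals, so the exchanged count for H3K4me3 can overstate the background here too. Per megabase, H3K4me1 regions numbered 26 and 25.3 on contigs, fewer than the 37.2 and 33.7 on numbered chromosomes, while H3K4me3 regions numbered 15.5 and 21.8, against 17.9 and 21.0. Of the H3K4me3 regions on contigs, 51.6% and 38.2% overlapped an H3K4me1 region. The widest on the contigs of Zv8 spanned 10800 bp.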

How the results depend on the processing

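Of 39 values computed under another setting, 29 stayed within 1.5 times the count, or 1 SD of the overlap or ratio, and 10 moved further. Of the settings, 28 were fixed before the data were examined and 11 were chosen after seeing the data. The values with a set left out are not among the 39. With 2 sets, each set alone always lies within 1 SD of their mean, so leaving a set out could not move the overlap or ratio. Several of the 29 lie close to the bound. They include H3K4me1 regions in thinned libraries, 30922 against 46060. Tiles with H3K4me3 above input at a pseudocount of 0.1 were 67624 against 45330. Tiles of 2 kb that differed between the marks were 92586 against 136694. The number 29 is therefore no measure of robustness. Counts of higher tiles cannot reverse, but the more frequent direction turned in both sets in 3 of 18 tile comparisons: with median-of-ratios scaling for H3K4me3 over input and over H3K4me1, and with a pseudocount of 0.1 for H3K4me1 over input. Each value is the mean of both sets. With a pseudocount of 0.1 the tiles with H3K4me1 above input rose from 43277 to 77340, the lower ones rising more, and those that differed between the marks from 136694 to 269256; with 2 kb tiles, of which there are fewer by construction, 23994 tiles had H3K4me1 and 28184 had H3K4me3 above input. Median-of-ratios scaling raised the tiles with H3K4me3 above input from 45330 to 72931. H3K4me1 regions fell from 46060 to 25003 at p of at most 1e-08, and to 28121 with the window's own input in the rate (chosen after seeing the data). The overlap of H3K4me3 with H3K4me1 regions fell from 58.4% to 47.9% in thinned libraries (also chosen after seeing the data), where fewer H3K4me1 regions, 30922, were called. Thinned and at p of at most 1e-08, added last, H3K4me1 regions fell to 13832 and the overlap to 34.0%. The cause of the other moves was not tested. With a set left out, the tile counts ranged from 42641 to 43913, 43166 to 47494 and 136290 to 137097, the regions from 44603 to 47517 for H3K4me1 and from 22849 to 27715 for H3K4me3, the overlap from 52.8% to 64.1%, and the ratio of centre to flank from 1.34 to 1.69. Summaries that need no shared position were compared within sets without a paired test. The tile models with and without a replicate block, the other set's input, regions shared by the sets and promoter windows were not run, since the sets lie on different assemblies, or for want of an annotation. Of simulated regions at 2 times a background smoothed over 10 kb, most were missed; this is another scale than the folds over a region's own input, which can be lower in called regions.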

Other observations

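H3K4me3 regions were denser near chromosome ends than elsewhere in both sets, while H3K4me1 regions were sparser there in replicate 1. Within 3 Mb of an end there were 24.5 H3K4me3 regions per Mb in replicate 1 and 32.4 in replicate 2, against 17.0 and 19.5 over the remaining length. The ends were denser on 21 and 24 of the 25 chromosomes, by a mean of 7.48 ± 6.90 and 12.7 ± 7.63 per Mb (SD over chromosomes), with a sign-flip permutation p of 1e-05 in each set, the smallest 100000 permutations can give (adjusted 2e-05 over 4 tests). For H3K4me1 the mean difference of ends from the rest was -4.58 ± 8.03 and -1.68 ± 9.25 per Mb, and the ends were denser on 7 and 11 chromosomes (permutation p = 0.00796, adjusted 0.0106, in replicate 1 and 0.374, adjusted 0.374, in replicate 2). Input reads per Mb at the ends were 1.03 and 0.826 times those elsewhere. The comparison was chosen after the densest megabases had been seen: H3K4me3 regions peaked in the first megabases of chromosome 22, with 93 regions from 1000001 to 2000000 of Zv7 and 86 from 2000001 to 3000000 of Zv8, against a median of 17 and 19 per megabase. H3K4me1 regions peaked on chromosome 23, with 167 from 21000001 to 22000000 of Zv7 and 147 from 22000001 to 23000000 of Zv8, against a median of 33 and 30.

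Mitochondrial DNA carries no histones, and its reads were rarer in the ChIP libraries than in input. In replicate 1 the input library had 1926 mitochondrial RPM, the H3K4me1 library 28.7 and the H3K4me3 library 49.5, so input was 67.1 times (95% interval 60.7 to 74.4) and 39.0 times (35.2 to 43.2) higher. In replicate 2 there were 120 mitochondrial reads in input, 3 in the H3K4me3 library and 0 in the H3K4me1 library, or 9.28, 0.321 and 0 RPM, so the sets differed in the number of such reads. Here RPM refers to all aligned reads. The H3K4me3 and input files of replicate 1 name the mitochondrial sequence in 2 ways, in successive parts, as if 2 listings had been joined, and within the parts, contigs left out, the input had 2105 and 2106 RPM and H3K4me3 53.2 and 55.7, so the joining does not account for the ratio. The H3K4me1 file of replicate 2 has no mitochondrial name, and whether such reads were left out of it is not known.

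Of the tests below, those of the H3K4me1 profile within H3K4me3 regions and of H3K4me3 reads mixed into input were chosen after the values they use had been seen. H3K4me1 reads were raised within H3K4me3 regions in both sets. If H3K4me3 chromatin carried into the H3K4me1 libraries were the whole cause, both marks would have the same profile, but the excess at 700 to 1000 bp relative to that at the centre was at least 3.47 times larger for H3K4me1 (86.7% against 17.1% in replicate 1 and 43.7% against 12.6% in replicate 2). A bias of read recovery shared by every library should vanish after division by input, and H3K4me1 to input remained 1.59 and 1.92 times higher at the centre than at 4 to 5 kb. A smaller carried-over part, which could fill the centre in replicate 2, stays open, as does a mixture of cells with one mark each; no biological explanation was tested.

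Input reads were also raised within H3K4me3 regions, which makes folds there lower than they would be against a flat input. H3K4me3 reads mixed into the input libraries, if the only cause, would leave little excess where H3K4me3 was not enriched. At H3K4me1-only regions the input excess of centre over flank was 124% and 130% of that at H3K4me3 regions, so an input excess also arose without H3K4me3 enrichment. H3K4me1 regions were called without the window's own input in the rate and may be picked for many reads of any library. The test therefore cannot exclude mixed reads as part of the rise within H3K4me3 regions. A bias of read recovery shared by every library was tested in windows outside all regions, picked for many input reads in a random part of the input. There H3K4me3 reads rose by 82.2% or more of the rise in the remaining input reads (84.2% in replicate 1), and H3K4me1 reads by 90.8% and 93.2%. This is consistent with such a bias, from how chromatin breaks or how reads align; these 2 sources were not separated.

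Chromosome 4 from its middle, 36000001, on in the Zv8 set was compared with 10 kb tiles of other chromosomes that had as many input reads. The median tile there had 9 input reads, against 103 elsewhere, which may leave too few to call a region. H3K4me3 regions reached 123% (95% Poisson interval 107% to 140%) of the number in matched tiles, so the low read number could account for their low density. H3K4me1 regions reached 46.0% (36.1% to 57.9%), which argues against the total of input reads per tile as the whole cause for H3K4me1. The bound set beforehand was 50%, which lies within the interval. The condition that the interval stay below 80% was added after the value had been seen. Tiles were not matched on how reads lay within them. Too few windows with enough reads to call H3K4me1 therefore stays open. In the Zv7 set the corresponding shares were 108% and 77.8%. No biological explanation was tested, and reads of repeated sequence that align to several places could not be followed in these data.

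A further hypothesis was that H3K4me1 lies on the side of an H3K4me3 region that holds less H3K4me3. With 21232 and 26040 regions turned by their H3K4me3 reads at 500 to 1500 bp, H3K4me3 to input was 1.52 and 1.59 times higher on the rich side. H3K4me1 to input on that side was 0.966 times the other side in replicate 1 and above 1 in replicate 2, a mean of 1.01. Before division, H3K4me1 reads were more numerous on the rich side in both sets, 365596 against 274171 and 406898 against 299345. Input reads were too, 156317 against 113242 and 303044 against 233898. Only the ratios to input went in opposite directions, so these data do not settle the hypothesis.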
